A study of Mus musculus with 12 samples.

How the data were processed

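The series holds 12 ATAC-seq libraries of mouse dorsal root ganglia, 3 in each of 4 groups: wild type and Silc1-/-, each after sham operation or sciatic nerve injury. Groups were taken from the genotype and treatment labels. The files used were 4 lists of peak summits, 1 per group. Per the submitters' processing notes, Bowtie2 and MACS2 were used with the mm10 build; their versions, the read filters and whether reads of the 3 libraries were pooled before calling are not given in the sources used here. No header or label states whether insertion positions were shifted for the transposase, which could move summits by a few bases, far less than the 200 bp used here to join them.

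Each deposited line gives a summit position and a score, which the authors' peak caller wrote on a −log10 scale of a p-value or q-value; which of these it is was not stated. The smallest deposited score was just above 1.30, which is −log10 of 0.05. Scores depend on depth and were used mainly to describe, rank or filter summits within a list. Exceptions were the naming rule, which took the lower score of the lists that hold a locus, and a locus's position, taken at its highest-scoring summit. Ranks were set side by side only over loci in all 4 lists. The files hold no read counts, so depth is unknown, and a list's length varies with it.

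Because each group has 1 list, no test between groups, no p-value and no paired fit could be made, and agreement between genotypes was the only repeat. Summits lying within 200 bp of the next were merged to loci. Sharing was the percent of a list's summits with a summit of the other list within 200 bp, beside the mean of 100 random circular shifts. Positions are 1-based. Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10. The table gives no strand, so "transcription start site" in the design fixed before the data were examined was replaced by either gene end. Summits on unplaced sequences and the mitochondrial genome, 154 to 179 per list, had no genes to be placed against and counted as intergenic.

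For gene lists, summits within 50 kb of either gene end were counted, scaled to the mean list length and compared as log2 ratios with a pseudocount of 1, which understates changes of genes with few summits. The median over members was placed among 10000 random lists of protein-coding genes, drawn within 20 bins of summit number. A count that also took in the interior of long genes was computed first and departed from the fixed design; it is kept as an alternative, so the reported count was run after those values had been seen. All list symbols but 1 were symbols of the table: Drgx is a synonym of Prrxl1, which left 22 sensory neuron markers. A B cell list was added after seeing the data.

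Genes and loci were named by a rule fixed before the data were examined: for each of 8 classes of loci, the 10 with the highest lower score, no summit of another list within 1 kb and on the autosomes or X, of which the text names a part; examples from each fixed gene list; and Silc1 and Sox11. Loci named for having no summit of another list within 10 kb, and genes named in the closing section by a gene-end rule, were chosen after seeing the data.

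The steps were tested on simulated data. All 9 planted classes of loci, 24900 loci in all, were recovered in full. The planted sites lay far apart and their summits moved by much less than the joining distance. This therefore checked the code and not the joining of close sites in the real lists. When real summits were dealt to the lists at random, 5.92% of 1200 combinations of gene list and contrast fell outside the central 95%. Each summit was dealt on its own, so summits that come and go together in the real lists were not imitated. The share outside by chance in the real lists may thus differ. For the wild-type injury contrast, with planted lists of 20 genes chosen by total summits, 13 of 20 were found at a fold of 1.5 and 20 of 20 at a fold of 2. A first version chose the planted genes by their sham count, which favours high denominators, and found 0 and 12 of 20.

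Alternatives were joining distances of 50, 500 and 1000 bp, scores of at least 5 and 10, equal list lengths (the 27279 highest-scoring summits of each), autosomes only, gene ends within 500 and 2500 bp, loci over 1 kb from a gene end, gene neighbourhoods of 10 and 100 kb, and a pseudocount of 0.5, each tried on its own. The planned motif comparison needs a genome sequence, which was not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.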

Results

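Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in lumbar dorsal root ganglia (DRG) of mice. These ganglia hold the cell bodies of sensory neurons whose axons run in the sciatic nerve, together with satellite glia, Schwann cells, vascular cells and resident immune cells. Wild-type mice and mice lacking Silc1, a long noncoding RNA, were compared after a crush of the sciatic nerve or a sham operation, which gave 4 groups of 3 libraries each. For each group 1 list of peak summits was analysed, so each value below belongs to 1 list, no spread between animals could be computed, and no difference between groups was tested. Read totals are not given in the files, so the sequencing depth behind each list is unknown. Intervals are 95% Wilson intervals and cover counting error only.

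The wild-type sham list was the shortest, with 27279 summits, and the wild-type injured list held 43841, or 1.61 times as many. In Silc1-/- ganglia the order was the opposite: the sham list held 48332 summits and the injured list 35815, a ratio of 0.741. The same directions were seen among summits with a score of at least 10, of which there were 9255 and 13308 in wild-type sham and injured, and 11098 and 8139 in Silc1-/- sham and injured. The score is the authors' own value for each peak, on a −log10 scale.

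Summits within 1 kb of an end of a protein-coding or long noncoding RNA gene made up 42.0% of the wild-type sham list (41.4 to 42.6) and 32.1% of the wild-type injured list (31.7 to 32.6). They made up 28.9% of the Silc1-/- sham list (28.5 to 29.3) and 32.2% of the Silc1-/- injured list (31.7 to 32.6). The longer list of each genotype thus had the smaller share at gene ends. Loci found in all 4 lists lay at gene ends in 55.6% of cases (54.8 to 56.4), against 12.3% (11.8 to 12.8) of loci found in the Silc1-/- sham list alone and 16.6% (16.0 to 17.3) of those found in the wild-type injured list alone. With lists of equal length, the injured minus sham difference was -0.763 percentage points in wild type and -2.07 in Silc1-/-, so the opposite directions did not hold at equal length.

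**Figure D1:**
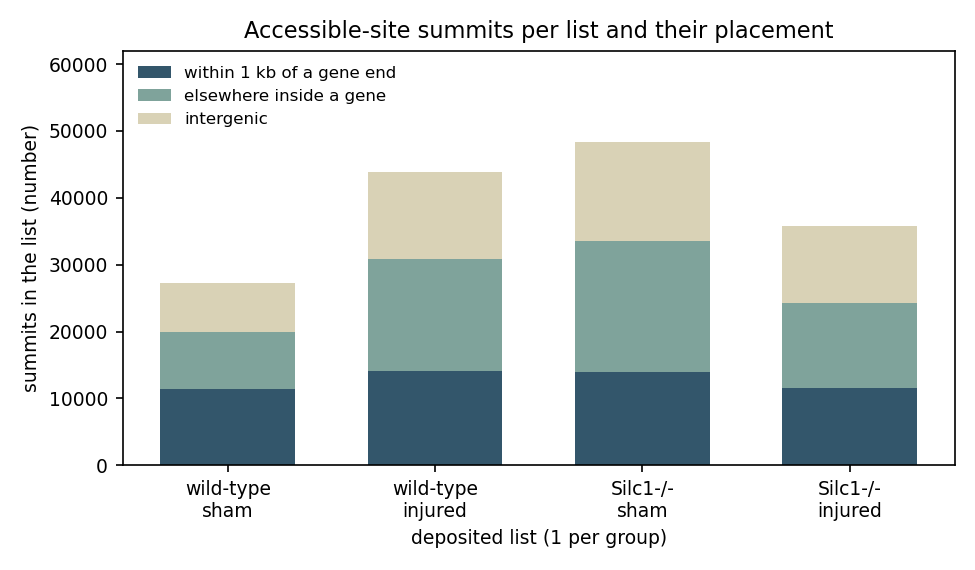
Number of summits (vertical axis) in each of the 4 deposited lists (horizontal axis), stacked by placement relative to protein-coding and long noncoding RNA genes. Each bar is 1 list without replicates; totals run from 27279 in wild-type sham to 48332 in Silc1-/- sham.

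The targeted gene and its neighbour Sox11, a transcription factor linked to axon regeneration, were examined first, since the study concerns regulation of regeneration by long noncoding RNAs. Silc1 is not a symbol of the gene table used and was taken to be Gm9866 (gene ID 636791, a long noncoding RNA at chromosome 12, 27140796 to 27160516, mm10), an assignment from general knowledge and not from the files. No list had a summit inside Gm9866 or within 1 kb of either end, and the nearest summit lay 22.6 kb away, so these lists could not check the genotype labels. All 4 lists had a summit in intergenic sequence between Gm9866 and Sox11, at positions 27242583 in wild-type sham (score 13.8), 27243189 in wild-type injured (22.2), 27242927 in Silc1-/- sham (22.7) and 27242985 in Silc1-/- injured (19.9). This site lay 91.1 to 91.7 kb from the nearer end of Sox11 (gene ID 20666, 27334268 to 27342718) and 82.1 to 82.7 kb from Gm9866. At the other end of Sox11, the wild-type injured list had a summit at 27342723 (score 7.44), the Silc1-/- injured list at 27342786 (5.28) and the Silc1-/- sham list at 27343080 (7.08), with a further one at 27341853 (5.21) inside the gene. The wild-type sham list had no summit there. The Sox11 summits of the injured lists fell in the class shared by both injured lists alone, because the nearest Silc1-/- sham summit was 294 bp away, beyond the 200 bp that joined summits.

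**Figure D2:**
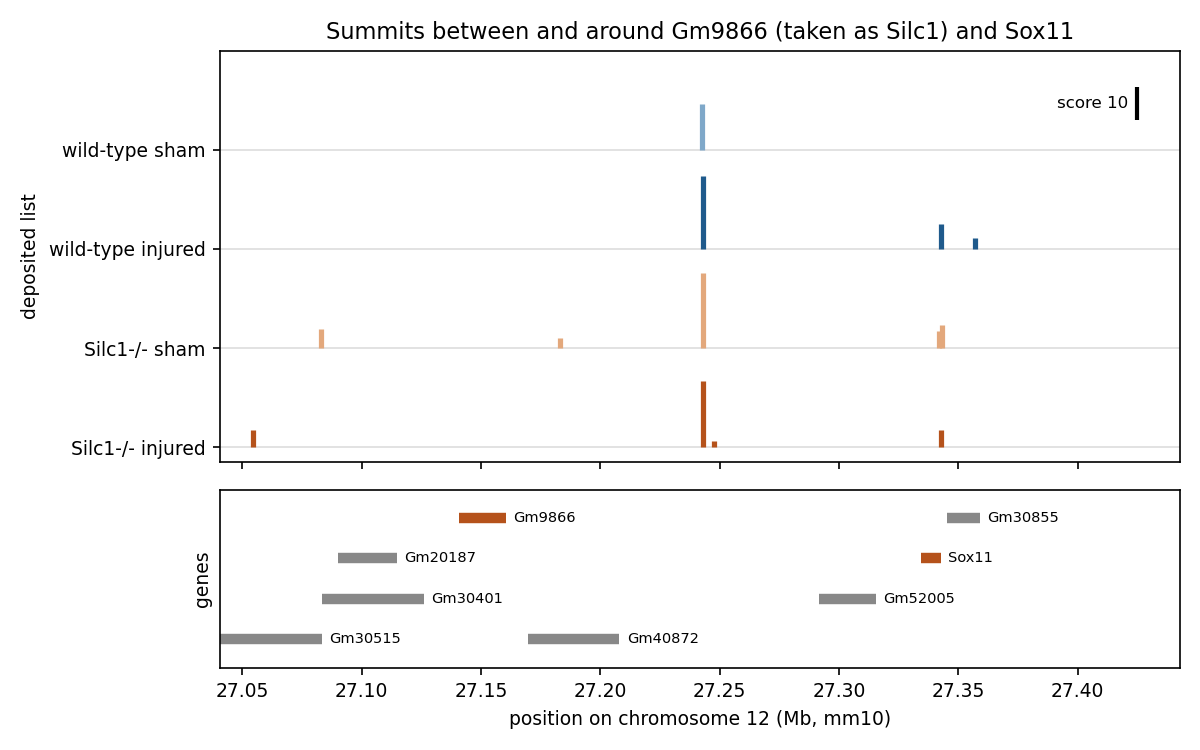
Positions of summits on chromosome 12 (horizontal axis, Mb, mm10) in each deposited list (rows), with bar height showing the authors' score against the scale bar of 10, above the annotated genes. A site between Gm9866 and Sox11 is present in all 4 lists, and the end of Sox11 has a summit in every list but wild-type sham.

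Lists shared far more summits than chance placement gave. Of the wild-type sham summits, 72.9% (72.4 to 73.4) had a wild-type injured summit within 200 bp, 68.9% (68.3 to 69.4) a Silc1-/- sham summit and 63.2% (62.6 to 63.8) a Silc1-/- injured summit; after moving the other list around each chromosome the shares averaged 0.729%, 0.796% and 0.594%. Of the Silc1-/- injured summits, 61.5% (61.0 to 62.0) lay near a Silc1-/- sham summit and 59.0% (58.5 to 59.5) near a wild-type injured summit. Averaged over both directions, lists of the same genotype shared 56.4%, lists of the same treatment 53.7% and lists with neither in common 55.1%. Over the 14347 loci with a summit in every list, Spearman's rho of the scores, computed across loci that are not independent replicates, was 0.862 between the wild-type lists and 0.835 between wild-type injured and Silc1-/- sham. It was 0.692 to 0.730 for each pair with the Silc1-/- injured list, which thus ranked the shared loci least like the others.

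The question of which sites open or close after nerve injury in both genotypes was addressed by merging all summits to 78381 loci. Of these, 2130 were found in both injured lists and neither sham list, and 1181 in both sham lists and neither injured list. By the naming rule, the highest-scoring loci in both injured lists lay in Thada (chromosome 17, position 84461022, lower score 84.6), nearest to 1700017L05Rik, 161557 bp away (chromosome 5, 77630414, 27.44), and in Orc5 (chromosome 5, 22495984, 21.0). Loci at 84462573 in Thada (lower score 70.1) and at 77629110, 160253 bp from 1700017L05Rik (12.9), were named for both sham lists. The nearest summits of the injured and sham lists there were 1419 and 1304 bp apart. Of the 10 named loci, 4 in both injured lists and 6 in both sham lists had a summit of another list within 10 kb. That distance was chosen after the data had been seen. The highest-scoring of the others in both injured lists lay in Gm52339, a long noncoding RNA gene (chromosome 18, 65119901, 14.4), in Kat2b, which encodes a histone acetyltransferase (chromosome 17, 53587284, 8.91), and in Gnai3, which encodes an inhibitory G-protein subunit (chromosome 3, 108134896, 8.23). In both sham lists they lay outside the nearest genes, which were Gm36412 (chromosome 3, 37481616, 16.7), Postn, which encodes the matrix protein periostin (chromosome 3, 54413457, 12.02), and Chd6, a chromatin remodeller (chromosome 2, 161214861, 7.86). Their distances from these genes were 60731, 22416 and 105775 bp. Of the regeneration-associated genes, 5 had a locus within 50 kb of a gene end in both injured lists alone and 8 in both sham lists alone. The highest-scoring of the former were at Sox11, Hspb1, a small heat shock protein (chromosome 5, 135887866, lower score 4.21), and Klf7 (chromosome 1, 64102415, 2.61). Of the latter they lay in Crem (chromosome 18, 3281112, 5.67), in Sema6a (chromosome 18, 47370437, 4.67) and near Atf3 (chromosome 1, 191224933, 3.21), each of these 3 with a summit of another list within 1 kb. The Atf3 locus lay outside the gene, which spans 191170296 to 191183333. For comparison with the 40 regeneration-associated genes, 7 of 25 housekeeping genes had such a locus in both injured lists alone and 2 in both sham lists alone. Among 20 immediate-early genes the numbers were 7 and 4. At equal list lengths, 1097 loci were in both injured lists alone and 1087 in both sham lists alone, so the excess of gained loci was not seen there. Cutting lists to equal length draws such counts together, so this does not show that length caused the excess. At scores of at least 5 the counts were 1007 and 420, and at scores of at least 10 they were 312 and 175, in lists that still differed in length.

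Within each genotype the balance was opposite. In wild type 23076 loci were present after injury and not after sham, against 6613 the other way, and in Silc1-/- ganglia 12843 against 25163. At equal lengths these counts became 9891 against 9612 and 10977 against 11044. Lists of equal length give nearly equal counts in both directions by construction, so this near balance is not a separate result. The opposite balance as deposited likewise largely restates the lengths of the lists.

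Loci that followed genotype numbered 3431 in both Silc1-/- lists alone and 1867 in both wild-type lists alone. The highest-scoring loci in both Silc1-/- lists lay in Gm46633 (chromosome 18, position 7033761, lower score 39.3) and nearest to Gm35912 (chromosome 16, 3236064, 36.0) and Gm35517 (chromosome 14, 74065964, 23.0), all long noncoding RNA genes. The last 2 loci lay 222357 and 37252 bp from these genes. Those in both wild-type lists lay nearest to AY036118 (chromosome 17, 39844161, 111.1) and A230045G11Rik (chromosome 17, 3020587, 92.8) and in Hrnr (chromosome 3, 93329966, 23.2), each with a summit of another list 1056 to 2255 bp away. Of the 10 named loci, 2 in both Silc1-/- lists and 6 in both wild-type lists had a summit of another list within 10 kb. The highest-scoring of the others in both wild-type lists lay in Hira, which encodes a histone chaperone (chromosome 16, 18958487, 14.3). At equal lengths the counts were 1816 and 2019, which turned the order around.

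Loci in exactly 2 lists were more often shared by lists of the same genotype than of the same treatment, but as deposited most often by lists with neither in common. As deposited, 5298 were shared by genotype, 3311 by treatment and 5648 by lists with neither in common. At equal lengths the counts were 3835, 2184 and 3190. Only there did genotype come first. At scores of at least 10 the counts were 986, 487 and 1419, and at joining distances of 50, 500 and 1000 bp lists with neither in common also shared most. Loci in a single list numbered 3486 for wild-type sham, 12545 for wild-type injured, 16576 for Silc1-/- sham and 8435 for Silc1-/- injured. At equal lengths these counts were 5857, 5788, 6456 and 6758, a smaller spread, though equal lengths draw such counts together. With summits joined within 50 bp they were 9497, 20491, 25415 and 16361.

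**Figure D3:**
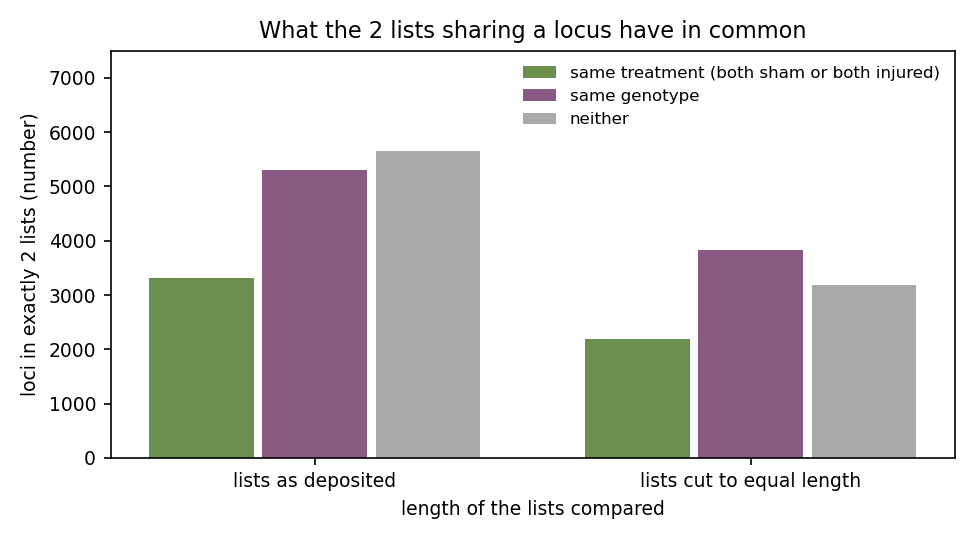
Number of loci found in exactly 2 of the 4 lists (vertical axis), grouped by what these lists have in common, for lists as deposited and for the highest-scoring summits of each list at equal length. Loci shared by lists of the same genotype outnumber those shared by lists of the same treatment, 3835 against 2184 at equal length. Lists with neither in common share the most loci as deposited, 5648, and 3190 at equal length.

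Whether injury moved the same sites in both genotypes was examined over the 14347 loci in all lists. The change in score rank from sham to injured in wild type correlated with that in Silc1-/- ganglia at r = -0.171 across loci, which are not independent replicates. The change from wild type to Silc1-/- in sham correlated with that in injured ganglia at r = 0.0523, and changes between pairs of lists with neither factor in common at r = -0.218. No positive correlation of the injury response between genotypes was thus seen in these ranks. Loci in all lists leave out, by construction, sites gained or lost after injury. Wild-type injured ranks were closer to Silc1-/- sham (Spearman's rho 0.835) than to Silc1-/- injured (0.692), and the depth behind each list is unknown. These correlations use the same lists and are not separate observations, so whether injury moved the same sites stays open.

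Among the highest-scoring loci of a single list, most had a summit of another list close by. Of the 10 loci named for each single-list class, 9 in wild-type sham, 8 in wild-type injured, 9 in Silc1-/- sham and 9 in Silc1-/- injured had a summit of another list within 10 kb. Sites nearest to Qrfprl on chromosome 6 were named for all 4 lists, at 65304733 in wild-type sham, 65298770 in wild-type injured, 65303040 in Silc1-/- sham and 65300817 in Silc1-/- injured, and sites nearest to Apba2 on chromosome 7 were likewise named for all 4.

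Groups of genes were compared by the number of summits within 50 kb of either gene end, scaled to list length. Of 60 combinations of 15 gene lists and 4 contrasts, 12 had a median outside the central 95% of 10000 matched random lists, where 3 would fall outside by chance; at equal list lengths 4 did, and 3 were outside in both with the same sign. The remaining one at equal lengths was skeletal muscle, a tissue that is not part of the ganglion, in Silc1-/- against wild type after injury (median 0.32, percentile 99.66). The 4 contrasts share the same 4 lists, so the combinations are not independent, and 1 unusual list can put a gene list outside in several contrasts. The percentiles describe these lists and are not tests. Summit counts below are unscaled sums over members, in which a summit near more than 1 member counts for each, while ratios are scaled to list length.

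Genes for sensory neuron channels, receptors and transmitters had more summits in Silc1-/- sham than in wild-type sham ganglia. The 22 genes had 131 summits against 40, the median log2 ratio was 0.98 (percentile 100), the fold of the scaled sums was 1.83, and 17 genes were higher and 4 lower. Grik1, a kainate receptor subunit, had 10 summits against 0, Oprm1, the mu opioid receptor, 7 against 1, and Kcna2, an axonal potassium channel, 6 against 0. At equal lengths the counts were 65 and 40 and the median was 0.58 (percentile 99.98), within 10 kb it was 0.11 (percentile 92.2), and at scores of at least 10 it was 0. Sensory neuron markers pointed the same way, with 133 summits against 54 near 22 genes and a median of 0.36 (percentile 99.9), including Prrxl1, a transcription factor of sensory neurons, at 7 against 1, and Pou4f1, another, at 7 against 1. At equal lengths their percentile was 97.0, inside the central range.

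After injury, the same channel genes had more summits in wild type, 96 against 40 (median log2 ratio 0.67, percentile 100), and fewer in Silc1-/- ganglia, 67 against 131 (median -0.45, percentile 0.065). Sensory neuron markers had 76 summits against 133 in Silc1-/- ganglia (median -0.28, percentile 1.31). At equal lengths all 3 medians were 0, while the sums were 48 against 40 for the channel genes in wild type, 52 against 65 in Silc1-/-, and 58 against 68 for the sensory neuron markers.

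Macrophage markers had 104 summits near 16 genes in wild-type injured against 51 in wild-type sham ganglia (median log2 ratio 0.51, percentile 99.9; fold of the scaled sums 1.27), with 11 genes higher and 4 lower. Itgam, an integrin of myeloid cells, had 9 summits against 4, Cx3cr1, the fractalkine receptor, 8 against 3, and Trem2, a receptor of phagocytes, 6 against 1. At equal lengths the counts were 66 and 51 and the median was 0.49 (percentile 99.7), but the list was inside the central range at scores of at least 5 (percentile 88.2) and at least 10 (95.3), and within 10 kb the median was 0 (percentile 49.3). In Silc1-/- ganglia the counts were 64 after injury and 85 after sham (median 0.01, percentile 38.4). Between the injured lists, macrophage markers had fewer summits in Silc1-/- than in wild type (median -0.52, percentile 0.205), which at equal lengths lay at percentile 3.54.

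Neutrophil markers, 8 genes, had sums of 57 in wild-type injured, 25 in wild-type sham and 26 in Silc1-/- injured ganglia, which come from 48, 22 and 23 distinct summits. The median log2 ratio of Silc1-/- to wild type after injury was -0.79 (percentile 0.17), with all 8 genes lower, and at equal lengths -0.66 (percentile 0.5). It was inside the central range within 10 kb (median -0.41, percentile 8.72) and at scores of at least 5 (percentile 4.03). Retnlg, a resistin-like protein of neutrophils, had 5 summits in wild-type injured and 2 in Silc1-/- injured, and Cxcr2, a chemokine receptor, 5 and 1. S100a8 and S100a9 are neighbours and share summits, so the members are not independent. For injury in wild type the median log2 ratio was 0.61, an increase (percentile 99.8), and lay at percentile 94.5 at equal lengths. T cell markers were lower in Silc1-/- injured than in wild-type injured ganglia (median -0.48, percentile 1.52), and mural cell markers higher (0.38, percentile 98.3) and higher after injury in Silc1-/- (0.33, percentile 97.6); none of these 3 lay outside the central range at equal lengths.

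Regeneration-associated genes lay inside the central range of medians in every contrast. Their median log2 ratios were 0.02 for injury in wild type (percentile 90.7), -0.12 for injury in Silc1-/- (2.75), -0.19 for Silc1-/- against wild type in sham (21.9) and -0.10 in injured ganglia (11.7). Summed over members, the last of these was -0.34 and lay outside (percentile 2.05), and within 100 kb injury in Silc1-/- lay at 2.07. Of the 40 genes, 26, 28, 27 and 25 had a summit within 1 kb of a gene end in wild-type sham, wild-type injured, Silc1-/- sham and Silc1-/- injured, and 22 had one in all 4 lists. Over all 21627 protein-coding genes these numbers were 10104, 11358, 11129 and 9975, and 8927 in all 4, so the lists ranked in the same order. Gal, which encodes the neuropeptide galanin, had 2, 9, 4 and 1 summits within 50 kb in that order, and Atf3, an injury-induced transcription factor, 8, 8, 9 and 7. As medians in lists as deposited, immediate-early genes, sterol biosynthesis genes, housekeeping genes and markers of satellite glia, Schwann cells, endothelium, fibroblasts and skeletal muscle also lay inside the central range in all 4 contrasts. Summed over members, immediate-early genes were lower in Silc1-/- sham than in wild-type sham (log2 ratio -0.64, percentile 1.24). For Silc1-/- against wild type in injured ganglia they lay at percentile 1.695 within 10 kb (median -0.28), 0.76 within 100 kb (-0.36) and 0.02 at scores of at least 5 (-0.51). At that score T cell markers lay at percentile 0 for injury in Silc1-/- (-0.86), and immediate-early genes at 0.94 (-0.30). For injury in wild type, endothelial markers lay at 99.71 within 100 kb (0.50) and Schwann cell markers at 2.255 with whole genes counted (-0.45). Sterol biosynthesis, housekeeping and skeletal muscle genes also each lay outside in some contrast under an alternative setting.

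**Figure D4:**
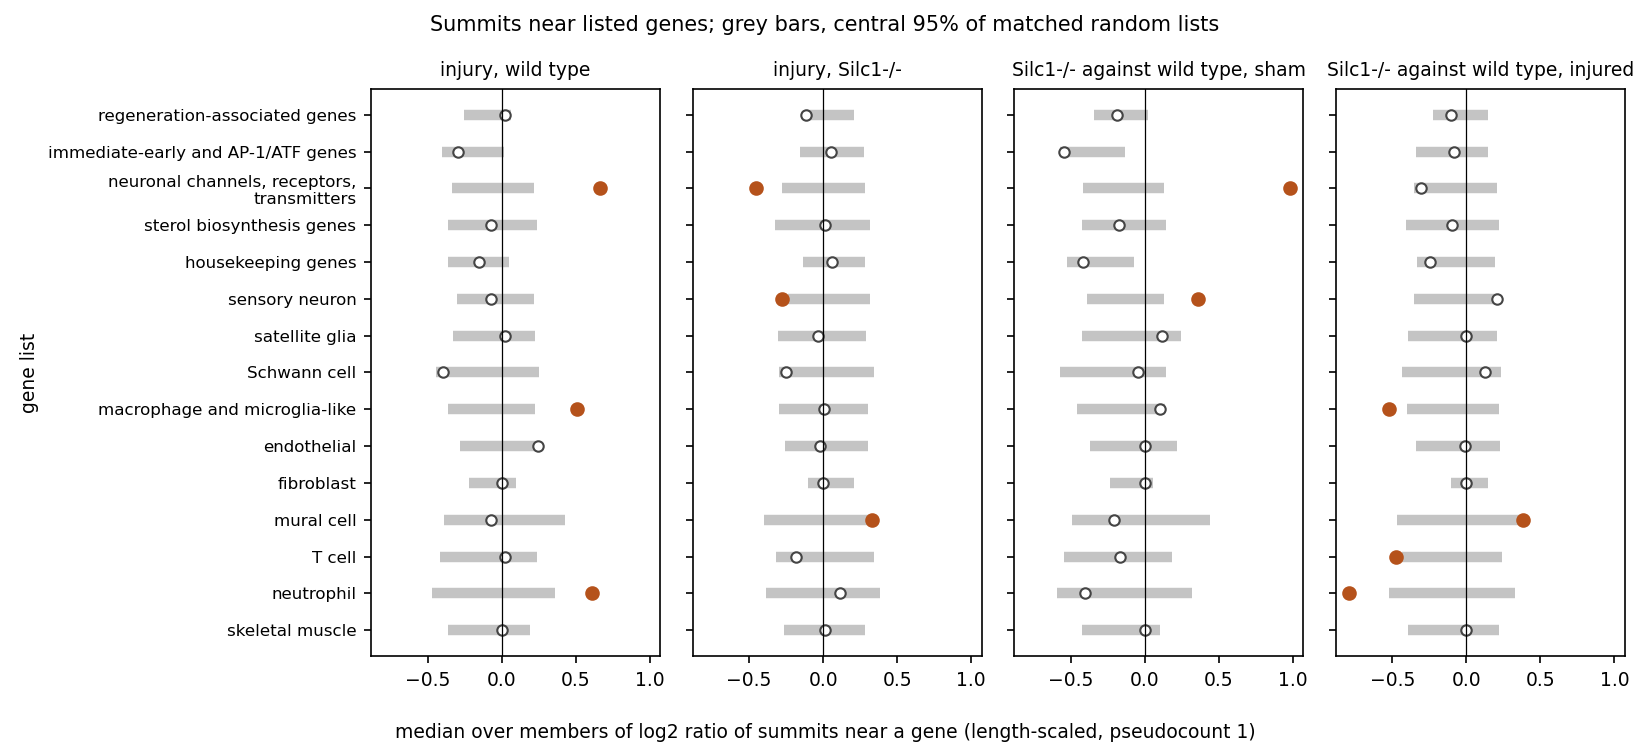
Median log2 ratio of length-scaled summit counts near the members of each gene list (horizontal axis, pseudocount 1) for 4 contrasts between lists (panels), with the central 95% of 10000 matched random lists as grey bars. Filled points lie outside that range, among them the neuronal channel genes at 0.98 in Silc1-/- sham against wild-type sham.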

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

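All tests of explanations in this part, and the bounds they use, were chosen after the results they bear on had been seen. Each group has 1 list, so none of the differences between groups given here was tested.

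List length was higher after injury in wild type (ratio 1.61) and lower in Silc1-/- ganglia (ratio 0.741), a difference in direction between genotypes. A list's length varies with sequencing depth, which is unknown, so these lists do not show whether depth, signal over background or the groups set these lengths, and no biological explanation was tested. The share at gene ends also moved in opposite directions, by -9.88 percentage points in wild type and 3.27 in Silc1-/-, and not at equal lengths (-0.763 and -2.07).

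Summits near sensory neuron channel genes differed in direction between genotypes and between treatments: median log2 ratios were 0.67 for injury in wild type and -0.45 in Silc1-/-, and 0.98 for Silc1-/- against wild type in sham and -0.31 in injured ganglia, the last inside the central range (percentile 3.77). At equal lengths the medians were 0 but for 0.58 in Silc1-/- sham against wild-type sham, while the sums after injury and sham were 48 and 40 in wild type and 52 and 65 in Silc1-/-, so whether injury differs in direction between genotypes stays open. For that excess in Silc1-/- sham, the percentile at equal lengths was 99.98, outside the central range. The bound that allows for all 60 combinations, 99.96, was passed only narrowly and was chosen after the results had been seen. Equal lengths also leave the unknown depth in place, so this percentile does not decide on list length or chance, which stay open. Gene length alone was argued against by the percentile of 100 among random lists matched on it too, a matching that changed percentiles of other combinations by up to 15.22 (another random seed, by up to 1.585) and took none of the 60 across the central range. The excess was no longer outside the central range at scores of at least 10 (median 0) or within 10 kb (median 0.11). A larger share of neuronal nuclei in these samples stays open: it would lower the lists of all 8 other cell types, and 3 of 8 lay below the 50th percentile, with none of the 8 outside the central range. An effect of Silc1 loss on neuronal chromatin may also account for it, and so may a difference between batches, since the library numbers in the labels run in separate blocks for the genotypes.

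Macrophage markers had medians of opposite sign for Silc1-/- against wild type in sham (0.11) and injured ganglia (-0.52), but the former lay inside the central range (percentile 92.1) and summed over members was -0.087. At equal lengths the medians were 0.216 and -0.415, both inside the central range (percentiles 96.5 and 3.54), so whether the direction differs stays open. For their higher counts after injury in wild type, the percentile was 99.72 at equal list lengths and 99.94 with matching on gene length. For the lower neutrophil counts in Silc1-/- injured than in wild-type injured ganglia these were 0.5 and 0.18. Without matching on gene length the percentiles were 99.9 and 0.17. Both results thus stayed outside the central range with it. None passed the bounds for all 60 combinations (0.0417 and 99.96), and skeletal muscle reached 99.66 at equal lengths, so list length, gene length and chance stay open. Blood left in the ganglia stays open: it could bring B cells as well, and the B cell list lay at percentile 23.91 after injury in wild type, which decides nothing. Recruitment of myeloid cells after injury, less of it in Silc1-/- mice, is a hypothesis that these lists cannot separate from a difference between dissections or batches.

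Mural cell markers also had medians of opposite sign, -0.073 for injury in wild type and 0.33 in Silc1-/-, and -0.21 for Silc1-/- against wild type in sham and 0.38 in injured ganglia. Both negative medians lay inside the central range (percentiles 36.3 and 22.4), all 4 were 0 at equal lengths, and the Silc1-/- sums were 26 after sham and 26 after injury, so the rise there came from scaling to list length.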

How the results depend on the processing

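No paired analysis was possible because each group has 1 list, and no replicate could be left out. The motif comparisons and GC resampling were not run. Leaving out the Silc1-/- injured list, the 1% highest scores, gene-length matching, whole-gene counting and sums over members were chosen after seeing the data. The length ratios kept their direction at scores of at least 5 and 10 and on autosomes. Of 84 alternative pairwise shares 72 left their counting interval; of 108 alternatives for the 12 gene list results outside the central range 60 stayed outside with the same sign and 48 did not, while 8 settings each put 1 to 4 other combinations outside. Unknown depth limits every comparison of list lengths. The cause of each change below was not tested, except that stricter scores and equal lengths leave fewer summits.

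At scores of at least 5, loci gained and lost numbered 1007 and 420, Silc1-/- and wild-type loci 1004 and 1127 (ratio 0.891, reversed), the genotype rank correlation was 0.081 and the Silc1-/- gene-end change 0.826 points. At scores of at least 10 these were 312, 175, 262, 724, 0.362 (reversed), 0.143 and -6.20 (reversed). At that score the wild-type gene-end change was -4.84 and the sham difference between genotypes -5.24. The Sox11 interval then held 1 summit in each of the 4 lists, wild-type sham included. At equal lengths, 1097 loci were gained (1.01 per lost), 1816 followed Silc1-/- (0.900 per wild type, reversed), the genotype rank correlation was 0.0829, and the gene-end changes were -0.763 in wild type, -2.07 in Silc1-/- (reversed) and -3.23 between genotypes in sham. At 1000 bp, 692 loci were lost and 1233 followed wild type. Over 1 kb from a gene end the genotype rank correlation was -0.000483 (reversed). Leaving out the Silc1-/- injured list gave 14960 gained and 2284 lost (6.55), and 20341 Silc1-/- and 3332 wild-type loci (6.11). Gained loci then rest on the wild-type injured list alone and Silc1-/- loci on the Silc1-/- sham list alone. Lost and wild-type loci still need both sham or both wild-type lists, so these ratios cannot be set against the earlier ones. Gene list combinations outside the central range numbered 4 at equal lengths, 7 at scores of at least 5, 4 at scores of at least 10 and 6 at 10 kb, against 12.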

Other observations

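The loci described here were picked by rules added after the data had been seen, within 1 kb of an end of a protein-coding gene and over 1 kb from summits of other lists, and no test was run on them. In order of score, loci in the wild-type injured list alone lay at ends of Hcls1, a signalling protein of blood cells (chromosome 16, position 36934942, score 20.8), Lilrb4a, an inhibitory receptor (chromosome 10, 51490916, 16.2), and 9530057J20Rik (score 14.8), the first 3 of 730 such loci. The first 2 in both wild-type lists lay at ends of Prkd2, a protein kinase (score 8.72), and Spry1, an inhibitor of growth factor signalling (8.65), of 153. The first 2 in both Silc1-/- lists lay at ends of Adprhl1 (7.18) and Rhbg, an ammonium transporter (7.14), of 133.

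The first 2 of 74 in both sham lists lay at ends of Snap25, a synaptic vesicle fusion protein (lower score 6.33), and Epha4, an ephrin receptor (5.59), which tied with 1700011L22Rik. The Snap25 locus lay 831 bp from its end and 68 bp from an end of the long noncoding RNA gene Gm32659. The first 2 of 96 in both injured lists lay at ends of Laptm5, a lysosomal membrane protein (7.49), and Mterf4, a mitochondrial protein (7.31), which tied with Eif3j2.

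The B cell list, also added after the data had been seen, lay inside the central range in all 4 contrasts, with medians of -0.19 and -0.32 for injury in wild type and Silc1-/-, and -0.26 and -0.15 for Silc1-/- against wild type in sham and injured ganglia.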
